A study of Rattus norvegicus with 18 samples.

How the data were processed

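The samples were RNA of CD146-sorted lung mesenchymal stromal cells from 6 rat pups, 3 of them exposed to 95% oxygen for 10 days and 3 kept in room air, with 3 technical arrays per pup. Per the labels, total RNA was extracted with a column kit, its quality was checked on a Bioanalyzer, and it was labelled with biotin by an Affymetrix whole-transcript sense target protocol. The authors deposited 1 table of 36685 probe sets by 18 arrays. Its values are on a log2 scale: the deposited values run from 0.134 to 12.36, and the highest corresponds to a linear intensity of 5269. The software, background correction, normalization method and summarization behind the deposited log2 values are not given in the sources used here. Array medians (4.522 to 4.594) and upper quartiles (7.137 to 7.203) lie close together, so the arrays had been brought to a common scale before deposit, and no further normalization was applied in the main analysis. Such scaling removes any shift in total RNA per cell, so each change is relative to the other genes of the array, whose median log2 fold change was −0.0072. Background on whole-transcript arrays compresses changes of dim genes.

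Probe sets were named from the platform annotation. Of the 36685 probe sets 18511 carry 1 gene symbol, 575 carry several and 17599 carry none; the latter are unnamed here. Of the 18511, 18394 matched a rat gene of the assembly GRCr8 by Entrez identifier, 117 did not and kept the annotation's symbol, and 0 symbols changed. No coordinates of that assembly are printed; it served for names and for which genes neighbour one another. Where a gene had several probe sets (291 genes) the one with the highest mean over all arrays was used, which left 18166 genes. Of the 183 genes past the threshold 3 had several probe sets, and their 3 other probe sets had the same sign but smaller changes. The log2 fold changes of the other and the used probe set were 0.178 and 1.09 for Tubb2b, −0.292 and −0.534 for Kcnk6, and 0.361 and 0.407 for Spats2l.

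The 3 technical arrays of a pup were averaged, so that each group had n = 3 pups. The comparison of hyperoxia with normoxia was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (two-sided, no covariates, 4 residual and 3.2 prior degrees of freedom), with Benjamini-Hochberg adjustment over 18166 genes and a threshold of 0.05. Means and SD are over the pup means of a group, log2 fold changes are hyperoxia minus normoxia, and SE is limma's moderated standard error. The labels give no litter, sex, array batch or scan day, so the groups may differ in such ways. No fit with a batch could be made. Pups share no numbers between groups, so there was no pairing of pups.

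The design, the alternatives, the gene lists and the rule for the genes to name were set before the data were examined. The rule took the 12 genes with the largest change upward and the 12 downward among those past the threshold whose pups did not overlap between groups, passing over symbols of uncharacterised loci, microRNAs, pseudogenes and olfactory and vomeronasal receptors. Of the genes past the threshold this left out the pseudogene Dram2-ps1 and the olfactory receptor genes Or11g26b and Or2f2, at −0.44, −0.33 and −0.44, too small a change to be among the 12. The rule added up to 4 members of each list by smallest p and a fixed panel of stromal and growth factor genes. Of that panel Eng and Acta2 are not analysed here, as no probe set in the annotation used here carries their symbol. The 32 lists held pathways (collagens and matrix glycoproteins, elastic fibres, matrix proteases, contractile genes, YAP and TEAD targets, pericyte genes, stromal surface proteins, lipofibroblast genes, secreted pro-angiogenic and anti-angiogenic factors, cytokines and NF-kB targets, interferon-stimulated genes, NRF2 and antioxidant genes, p53 targets and senescence, cell cycle, hypoxia and glycolysis, TGF-beta and BMP, Wnt, FGF and PDGF, lung mesenchyme transcription factors and hedgehog, unfolded protein response, cholesterol and fatty acid synthesis, oxidative phosphorylation, immediate early genes). They also held markers of other cell types (endothelial, epithelial, leukocyte, mesothelial, glial and neural, cartilage, muscle, sex-linked). Lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over 31 lists, and again with an estimated correlation, with camera on ranks and with fry. For each list gene p-values were also adjusted over the list alone.

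The fit was tested on simulated data with the real genes' means and with variances drawn from limma's fitted prior, in which 200 of 18166 genes were changed in 3 against 3 pups. Over 5 runs it called 61.6% of genes changed by 0.5 log2 units and 95.8% of those changed by 1, with 4.26% of calls on unchanged genes and 0 calls of the wrong sign. Camera called 1 list in 10 runs without change and called the list shifted by 0.3 log2 units in 10 of 10 runs. The simulation drew genes independently, so it does not cover correlation between genes of a list or pup effects that many genes share. Its variances came from the prior that the fit itself assumes, so a share of false calls near the threshold was built in. These rates need not hold for the real data.

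Alternatives tried were quantile normalization, subtraction of array medians, filters at the 25th and 50th percentile of the mean level, the mean of a gene's probe sets and every probe set on its own. Others were eBayes with a trend and with a robust trend, array weights, and all 18 arrays with the pup as a random block, with and without the technical array number, or taken as independent. The rest were single technical arrays, the median of the technical arrays, other thresholds, other set tests, and each pup left out in turn. The fit without technical array 2 of hyperoxia pup 13-3 was added after the data were seen. No array was left out of the main analysis.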

Results

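Gene expression was measured on Affymetrix whole-transcript arrays in mesenchymal stromal cells grown from the lungs of Sprague-Dawley rat pups and sorted for CD146. Mesenchymal stromal cells are adherent, fibroblast-like cells that support the neighbouring epithelium and vessels, and CD146, the product of Mcam, is a surface glycoprotein of cells around vessels. Of the 6 pups, 3 breathed 95% oxygen for the first 10 days of life (hyperoxia) and 3 breathed room air (normoxia). High oxygen in newborn rodents is a model of bronchopulmonary dysplasia, the chronic lung disease of preterm infants. Cells were isolated on postnatal day 12 (the age field of the labels gives 12.5) and those of both groups were handled alike from then on, in 5% oxygen, so the arrays read cells at passage 2 after 10 to 12 days of culture away from the exposure. The question was whether high oxygen after birth left a difference in the expression of resident lung stromal cells. The RNA of each pup was run on 3 technical arrays, 18 arrays in all, and the replicate was the pup (n = 3 pups per group), with the mean of its 3 arrays as its value.

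Array medians lay between 4.52 and 4.59 log2 units and single values between 0.134 and 12.36. Over all 36685 probe sets, Pearson's r between technical arrays of 1 pup averaged 0.995. Between single arrays of different pups it averaged 0.993 within a group and 0.991 across the groups. The median SD was 0.086 log2 units among the technical arrays of a pup and 0.09 among the pups of a group. The spreads were close, so both the number of pups and the noise of single arrays bear on the precision. As a yardstick for genes without expression, 1344 olfactory and vomeronasal receptor genes had a median level of 2.29 and a 95th percentile of 4.45.

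Cells from hyperoxia pups had a higher signal at the probe sets of the class I histocompatibility genes RT1-CE16 and RT1-CE15, and higher RNA of the serotonin receptor gene Htr1b and of the retinoic acid hydroxylase gene Cyp26b1. They had lower RNA of Nt5e, which encodes the adenosine-forming ectonucleotidase CD73, of the protease-activated receptor genes F2rl1 and F2rl2, and of the lung mesenchyme transcription factor genes Tbx4 and Meox2. In all, 183 of 18166 genes passed an adjusted p of 0.05 in limma, 72 higher (39.3%) and 111 lower in hyperoxia. The median change among them was 1.53-fold, and 34 changed at least 2-fold, 21 upward and 13 downward. In each of the 183 the 3 hyperoxia pups lay all above or all below the 3 normoxia pups. Passing the test with 3 against 3 pups nearly requires this, so it adds no support to the calls. Of all genes 20.3% were separated in this way, against 10% by chance. The first principal component of the pup means held 44.4% of the variance and separated the groups, with scores of 5.12 to 19.2 in hyperoxia and −17.6 to −7.11 in normoxia.

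**Figure D1:**
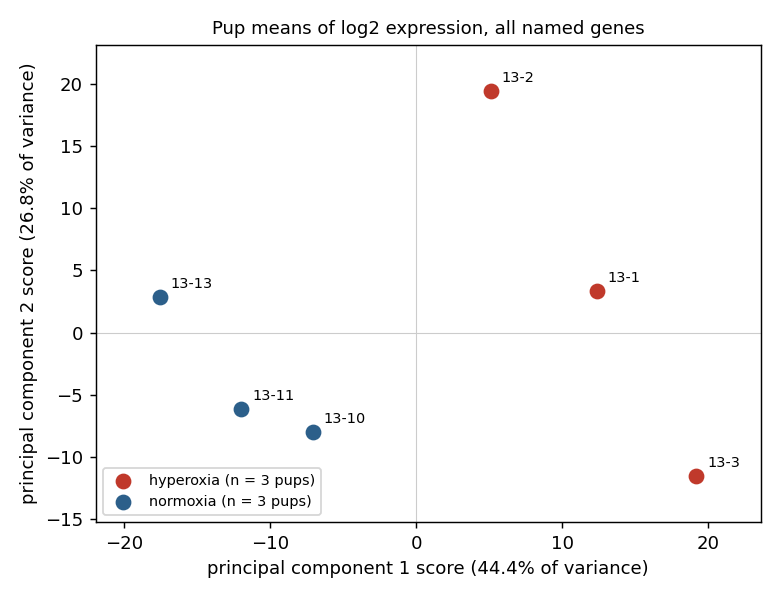
Scores of the 6 pups on the first 2 principal components of their mean log2 expression over 18166 genes, 1 point per pup, coloured by group. The hyperoxia pups sit at 5.12 or above on the first component (44.4% of the variance) and the normoxia pups at −7.11 or below; on the second (26.8%) hyperoxia pup 13-2 is the highest, at 19.4.

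The count of 183 depended on which pups were in the fit. It was 51 without hyperoxia pup 13-1, and 36, 21 and 18 without normoxia pups 13-10, 13-11 and 13-13, but 263 and 189 without hyperoxia pups 13-2 and 13-3. Which direction held more calls also depended on the pups: in the first 4 of these fits 51%, 58.3%, 66.7% and 77.8% of the genes past the test were higher in hyperoxia, and in the other 2 it was 38% and 45%. Of the 42 genes past the test that are named here by a rule set beforehand, 33 lost their call in at least 1 fit that left out a pup. RT1-CE16, RT1-CE15, Dpp4, Cyp26b1, Sprr1a, Gpr15lg, Nlrp1a, Wwc1 and Fgfr3 kept it in every setting in which calls were followed gene by gene. That leaves out the fit of every probe set on its own and the other thresholds. Fgfr3, at 1.70-fold, does not reach the threshold of 2-fold.

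Among the genes that rose, RT1-CE16 stood at 5.72 ± 0.13 in hyperoxia (SD, n = 3 pups) against 2.94 ± 0.47 in normoxia, a log2 fold change of 2.79 (SE 0.22, adjusted p = 0.00453). RT1-CE15 stood at 7.02 ± 0.23 against 4.39 ± 0.20, a change of 2.64 (SE 0.14, adjusted p = 0.00179). These are near-identical members of a polymorphic gene cluster, so the gene behind each probe set is uncertain, and the other 8 named RT1-CE genes had a median log2 fold change of 0.072, none past the test. Htr1b was 5.29-fold higher, at 8.39 ± 0.39 against 5.99 ± 0.32 (log2 fold change 2.40, SE 0.22, adjusted p = 0.00985). Cyp26b1, which clears retinoic acid, rose from 5.92 ± 0.038 to 7.27 ± 0.052 and had the smallest adjusted p of all genes, 0.000614 (log2 fold change 1.35, SE 0.055). Dpp4, the CD26 peptidase that trims chemokines and incretins, rose from 3.59 ± 0.12 to 5.03 ± 0.15 (log2 fold change 1.44, SE 0.097, adjusted p = 0.00339). The procollagen peptidase gene Adamts3 rose by 1.90 log2 units (SE 0.29, adjusted p = 0.0378). The laminin receptor subunit gene Itga6 rose by 1.27 (SE 0.13, adjusted p = 0.0148), as did Sncg, which encodes gamma-synuclein (SE 0.19, adjusted p = 0.0367). The uroplakin gene Upk1b rose by 1.47 (SE 0.18, adjusted p = 0.0213). The neuronal adhesion gene Slitrk5 rose by 1.84, the Toll-like receptor relative Cd180 by 1.38 and the cytochrome P450 gene Cyp3a9 by 1.30. In normoxia RT1-CE16, RT1-CE15, Slitrk5, Dpp4 and Cd180 all lay below 4.45, the 95th percentile of the receptor genes, a range in which array background compresses folds.

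Among the genes that fell, Fgf12, an intracellular FGF homologue that binds sodium channels, stood at 5.32 ± 0.44 in hyperoxia against 7.26 ± 0.34 in normoxia (SD, n = 3 pups), a log2 fold change of −1.94 (SE 0.24, adjusted p = 0.0213). F2rl2 and F2rl1, receptors cleaved by thrombin, trypsin and related proteases, changed by −1.73 (SE 0.24, adjusted p = 0.0307) and −1.05 (SE 0.13, adjusted p = 0.0213). Nt5e stood at 9.03 ± 0.27 against 10.38 ± 0.18, a change of −1.36 (SE 0.15, adjusted p = 0.0171), and Enpp3, another ectoenzyme that splits extracellular nucleotides, changed by −1.12 (SE 0.17, adjusted p = 0.0367). Sprr1a, a cornified envelope gene, changed by −1.54 (SE 0.11, adjusted p = 0.00387). Gpr15lg, the ligand of the chemoattractant receptor GPR15, stood at 9.69 ± 0.14 against 10.88 ± 0.086 (log2 fold change −1.18, SE 0.084, adjusted p = 0.00387). The inflammasome sensor gene Nlrp1a changed by −1.11 (SE 0.091, adjusted p = 0.00552). Also lower were Rtn4rl2, a Nogo receptor relative (−1.28), the sarcomere gene Klhl41 (−1.19), the oxysterol hydroxylase gene Cyp7b1 (−1.19) and Efcab2 (−1.02), each with an adjusted p between 0.0171 and 0.0367.

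**Figure D2:**
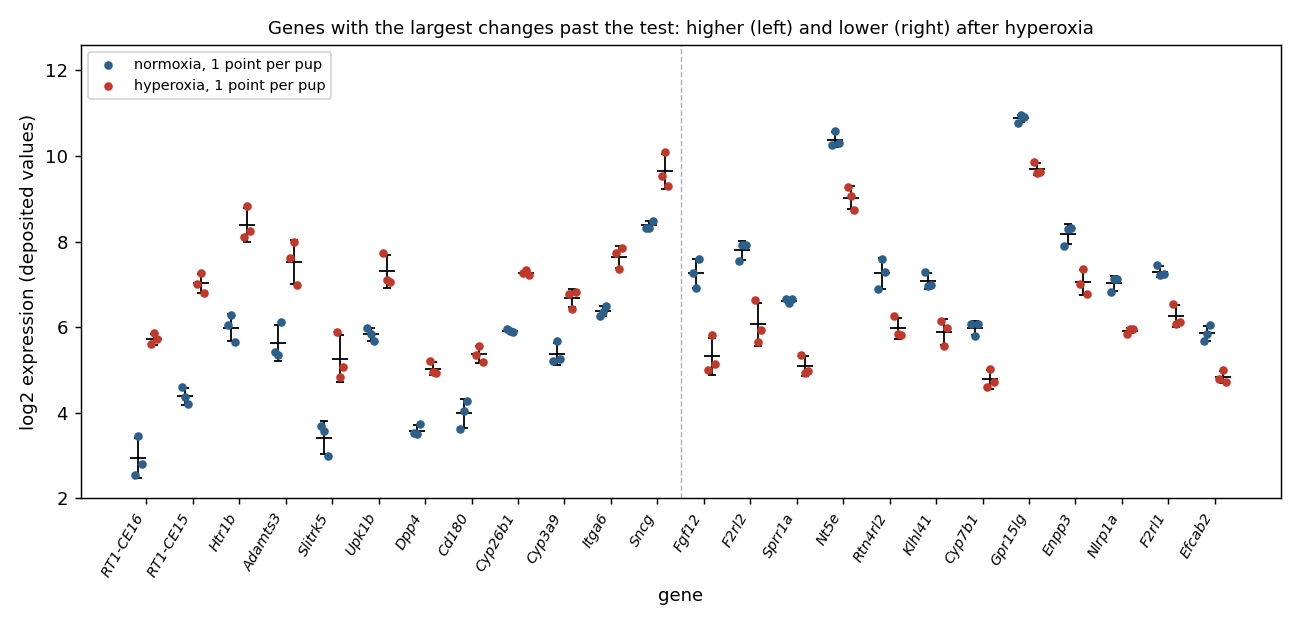
Log2 expression of the 12 genes with the largest changes upward (left of the dashed line) and the 12 downward (right) among those past the test, 1 point per pup (mean of 3 technical arrays), with the group mean and SD as bars. The 3 hyperoxia pups lie all above the 3 normoxia pups on the left and all below them on the right, as the rule that chose the genes required. RT1-CE16 shows a change of 2.79 log2 units in probe set signal. Its normoxia mean, 2.94, lies below 4.45, the 95th percentile of the receptor genes, a range in which array background compresses folds. The gene behind this probe set is uncertain, so neither the size of its RNA change nor the order of the genes is exact.

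Surface and growth factor genes fixed in advance for these cells gave mixed values. A single value beside a gene's name is its log2 fold change, hyperoxia over normoxia. Mcam, the gene of the sorting antigen, stood at 9.62 ± 0.046 in hyperoxia and 9.47 ± 0.091 in normoxia (SD, n = 3 pups; adjusted p = 0.372). Of the stromal surface genes, Nt5e fell as above, while Thy1 (0.055, adjusted p = 0.836), Pdgfrb (0.081, adjusted p = 0.627) and Pdgfra (−0.60, adjusted p = 0.17) did not pass. Fgf10, a mesenchymal signal for epithelial branching, just missed the threshold at 7.12 ± 0.36 against 8.25 ± 0.26 (log2 fold change −1.13, SE 0.20, adjusted p = 0.054). Eln, which encodes tropoelastin, had a log2 fold change of 1.01 with a wide error (SE 0.37, adjusted p = 0.276), as had Bmp4 (1.01, SE 0.24, adjusted p = 0.126). Vegfa (−0.18, adjusted p = 0.288) and Cdkn1a (0.064, adjusted p = 0.802) did not pass.

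Of 31 gene lists fixed in advance and tested with camera at a preset correlation between genes of 0.01, 8 passed an adjusted p of 0.05, 2 toward higher and 6 toward lower values in hyperoxia. None of them held with a correlation estimated from these pups. There the lowest adjusted p was 0.621 and 0 lists had an unadjusted p under 0.05. That estimate rests on 6 pups and 4 residual degrees of freedom, so the test has little power. The lipofibroblast list had an estimated correlation of −0.026, below the preset value, yet its unadjusted camera p went from 0.0104 to 0.0528. Losing a call there is thus no proof that correlated genes had made it. For the cell cycle and immediate early lists, however, the estimated correlations were 0.83 and 0.561, far above the preset value. With fry, which does not compare a list with other genes, 0 lists passed for direction (lowest adjusted p 0.112; 9 at an unadjusted p under 0.05) and 24 passed for change in either direction. With camera on ranks 4 passed: the cell cycle, immediate early, contractile, and cholesterol and fatty acid lists. Other splits of the 6 pups gave up to 7 lists with the preset correlation, and without hyperoxia pup 13-3 only the contractile (adjusted p = 0.0378) and epithelial (adjusted p = 0.0212) lists passed.

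The transcription factor and hedgehog genes of lung mesenchyme held the most single-gene calls of these 8 lists: of 27 measured, 4 fell and 23 did not pass, with 20 of the 27 values below 0 (adjusted over the list alone, 6 lower and 0 higher). Tbx4, a T-box factor of lung mesenchyme, stood at 7.63 ± 0.16 against 8.57 ± 0.041 (SD, n = 3 pups; log2 fold change −0.94, SE 0.086, adjusted p = 0.00985). The homeobox gene Meox2 changed by −0.94 (SE 0.12, adjusted p = 0.0213), the nuclear receptor gene Nr2f1 by −0.52 (SE 0.066, adjusted p = 0.0213) and Hoxa4 by −0.36 (SE 0.055, adjusted p = 0.0378). Hoxa4 lost its call in 10 of 21 settings, with a change from −0.48 to −0.17 and an adjusted p up to 0.468. The list's own adjusted p was 0.00595 with the preset correlation. It lost the call with an estimated correlation (adjusted p = 0.621), with fry (0.112), on ranks (0.0594) and without hyperoxia pup 13-3 (0.0712). It kept the call without each of the other pups (0.00255 to 0.0213), after quantile normalization (0.00623) and after subtraction of array medians (0.0121).

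Secreted pro-angiogenic factors had 1 of 25 measured genes past the test: Kitlg, the ligand of the KIT receptor, fell by 0.85 log2 units (SE 0.08, adjusted p = 0.00985). In the list 18 values were below 0, among them Fgf10, Fgf7 (−0.51) and Fgf2 (−0.39), which did not pass. Adjusted over the list alone, 4 were lower and 2 higher (list adjusted p = 0.0187, and adjusted p = 0.644 with an estimated correlation). The pro-angiogenic list's adjusted p was 0.113 without hyperoxia pup 13-3 and 0.0753 without normoxia pup 13-11. Of 14 lipofibroblast genes, which mark the lipid-storing fibroblast of the alveolar wall, 0 passed, with 11 below 0. Fgf10 and Tcf21 (−0.46) were lower in value and Pparg was higher (0.60, adjusted p = 0.0673). Adjusted over the list alone, 5 were lower and 1 higher (list adjusted p = 0.0404, and adjusted p = 0.621 with an estimated correlation). The lipofibroblast list's adjusted p was 0.114 without hyperoxia pup 13-3, 0.0829 without normoxia pup 13-10 and 0.0852 without normoxia pup 13-13. It was 0.0534 after quantile normalization and 0.0909 after subtraction of array medians.

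Contractile and myofibroblast genes had 13 of 16 values below 0 and 0 past the test, led by the smooth muscle actin gene Actg2 (−0.54, SE 0.10, adjusted p = 0.0675), the serum response factor coactivator gene Myocd (−0.43, adjusted p = 0.0824), Itga8 (−0.38) and Lmod1 (−0.47). Adjusted over the list alone, 4 were lower and 0 higher (list adjusted p = 0.00486, and adjusted p = 0.621 with an estimated correlation). Of 21 genes of cholesterol and fatty acid synthesis 0 passed and 17 had values below 0, such as Msmo1 (−0.45, adjusted p = 0.0679), Dhcr7 (−0.38) and Idi1 (−0.36), whereas Acaca was at 0.26. Adjusted over the list alone, 4 were lower and 1 higher (list adjusted p = 0.00515, and adjusted p = 0.644 with an estimated correlation, 0.119 without hyperoxia pup 13-3).

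Cell cycle genes had 37 of 40 values above 0, with a median log2 fold change of 0.16, and 0 passed, whether over all genes or adjusted over the list alone. Tyms (0.34, adjusted p = 0.164), Melk (0.39, adjusted p = 0.214), Ccnb1 (0.56, adjusted p = 0.247) and Ccnb2 (0.28, adjusted p = 0.27) had the smallest p-values. The list adjusted p was 1.02e-05, and adjusted p = 0.644 with an estimated correlation between genes (the correlation itself was 0.83). Relative to the mean of all pups the list stood at 0.31 in hyperoxia pup 13-3, 0.044 in 13-1 and −0.11 in 13-2, against −0.21 to −0.0089 in the normoxia pups, and without pup 13-3 its adjusted p was 0.107. Immediate early genes, the first to respond to serum or stress, had 15 of 19 values below 0 and 0 past the test (adjusted over the list alone, 1 lower and 0 higher). Jun was at −0.27 (SE 0.055, adjusted p = 0.0827), Myc at −0.21, Nr4a2 at −0.69 and Klf4 at −0.62. The list adjusted p was 0.00515, and adjusted p = 0.644 with an estimated correlation (the correlation itself was 0.561). This list stood at −0.62 in hyperoxia pup 13-3, 0.23 in 13-1 and −0.093 in 13-2, against 0.039 to 0.27 in normoxia, and without pup 13-3 its adjusted p was 0.25.

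Among matrix genes Ltbp4 and Ctsk fell and Plat rose. Of 27 collagens and matrix glycoproteins 0 passed and 18 had values below 0, such as Vcan (−0.28, adjusted p = 0.1), Col4a2 (−0.29) and Col4a1 (−0.26), with Col5a3 at 0.29. The set missed the threshold at an adjusted p of 0.0592, with 8 lower and 1 higher when adjusted over the list alone. It came to pass without hyperoxia pup 13-1 (adjusted p = 0.0452) or 13-2 (adjusted p = 0.002) and without normoxia pup 13-11 (adjusted p = 0.0119), but stood at 0.685 without hyperoxia pup 13-3, 0.107 and 0.25 without normoxia pups 13-10 and 13-13, and 0.644 with an estimated correlation. Relative to the mean of all pups this list stood at −0.317 in hyperoxia pup 13-3, −0.097 in 13-1 and 0.151 in 13-2, against 0.0225 to 0.211 in normoxia. Of 19 genes of elastic fibre assembly, Ltbp4, which binds latent TGF-beta and organises elastin, fell from 9.06 ± 0.056 to 8.12 ± 0.27 (SD, n = 3 pups; log2 fold change −0.94, SE 0.13, adjusted p = 0.029). The other 18, with Mfap5 at −0.46, Eln as above and Loxl1 at 0.19, did not pass. As a set these genes had an adjusted p of 0.337, with 1 lower and 0 higher when adjusted over the list alone, and 0.024 without hyperoxia pup 13-2. Of 27 matrix proteases and inhibitors, the collagen-degrading protease gene Ctsk fell by 0.67 (SE 0.087, adjusted p = 0.0231) and the tissue plasminogen activator gene Plat rose by 0.66 (SE 0.099, adjusted p = 0.0367). The other 25, among them Timp4 (0.34) and Adamts4 (−0.32), did not pass. Over the list, camera gave an adjusted p of 0.582, and the calls adjusted over the list alone were 2 lower and 2 higher.

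In signalling lists single genes passed in both directions. Of 26 FGF and PDGF signalling genes the receptor gene Fgfr3 rose by 0.76 (SE 0.061, adjusted p = 0.00516) and Spry1, an inhibitor of receptor signalling, fell by 0.77 (SE 0.10, adjusted p = 0.0221). The other 24, with Fgf10 and Fgf7 among them, did not pass. Camera returned an adjusted p of 0.852 for the list, and 6 lower and 5 higher passed when adjusted over the list alone. Of 35 Wnt signalling genes Wnt5a fell by 0.55 (SE 0.056, adjusted p = 0.0148). The other 34 did not pass, Fzd1 (−0.38, adjusted p = 0.0503) and Sfrp4 (0.48, adjusted p = 0.0584) by little and Sfrp1 at −0.49. As a set these genes had an adjusted p of 0.321, with 3 lower and 1 higher when adjusted over the list alone. Of 32 TGF-beta and BMP genes 0 passed, with Tgfbr3 at −0.67 (adjusted p = 0.0653), Acvrl1 at −0.27 and Smad6 at 0.34. Over the list, camera gave an adjusted p of 0.393, and the calls adjusted over the list alone were 2 lower and 1 higher. Of 16 YAP and TEAD targets, Wwc1, which encodes the Hippo pathway scaffold KIBRA, rose by 1.08 (SE 0.067, adjusted p = 0.00339), and Nt5e and the tissue factor gene F3 (−0.37, SE 0.054, adjusted p = 0.0367) fell. The other 13, with Ankrd1 at 0.32, did not pass. Camera returned an adjusted p of 0.221 for the list, and 4 higher and 3 lower passed when adjusted over the list alone. Of 20 secreted anti-angiogenic factors 0 passed, with Sema3e (0.76) and Sema3a (0.93) both at an adjusted p of 0.056, Col18a1 at 1.17 and Slit3 at −1.11. As a set these genes had an adjusted p of 0.356, with 4 higher and 3 lower when adjusted over the list alone.

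Stromal identity lists were split as well. Of 20 pericyte genes Cd248, which encodes endosialin, fell by 0.43 (SE 0.064, adjusted p = 0.0367) and 19 did not pass, with Cspg4 at 0.62, Cox4i2 at −0.32 and Kcnj8 at −0.42. Over the list, camera gave an adjusted p of 0.459, and the calls adjusted over the list alone were 2 lower and 1 higher. Of 16 mesenchymal stromal surface genes Nt5e fell and 15 did not pass, with Bst1 at −0.47, Nes at 0.58 and Pdgfra as above. Camera returned an adjusted p of 0.321 for the list, and 3 lower and 1 higher passed when adjusted over the list alone.

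Inflammatory and stress lists held few calls. Of 31 cytokine, chemokine and NF-kB genes Il1rn, which encodes the interleukin-1 receptor antagonist, rose from 8.61 ± 0.068 to 9.78 ± 0.40 (SD, n = 3 pups; log2 fold change 1.16, SE 0.18, adjusted p = 0.0378). The other 30 did not pass, with Cx3cl1 at 1.24, Birc3 at −0.41 and Ccl20 at −0.39. As a set these genes had an adjusted p of 0.147, with 2 higher and 2 lower when adjusted over the list alone, and 0.0213 without hyperoxia pup 13-1. Of 31 interferon-stimulated genes the immunoproteasome subunit gene Psmb8 fell by 0.65 (SE 0.094, adjusted p = 0.0347) and 30 did not pass, with Ifit2 at −0.72, Stat2 at −0.23 and Ifi44 at −0.53. Over the list, camera gave an adjusted p of 0.227, and the calls adjusted over the list alone were 1 lower and 0 higher. Of 23 p53 target and senescence genes Cdkn2b, which encodes the cyclin-dependent kinase inhibitor p15, rose by 0.54 (SE 0.091, adjusted p = 0.0485) and 22 did not pass, with Igfbp5 at −1.11, Zmat3 at 0.20 and Plk2 at −0.28. That list had a median of 0.021 and a mean of −0.053, and camera placed it upward. Camera returned an adjusted p of 0.594 for the list, and 2 higher and 1 lower passed when adjusted over the list alone. Of 33 NRF2 and antioxidant genes 0 passed, with Hmox1 at −0.42 (adjusted p = 0.0939), Osgin1 at 0.46, Gstm1 at 0.30 and Gstp1 at 0.43. As a set these genes had an adjusted p of 0.262, with 3 higher and 1 lower when adjusted over the list alone. None of the genes of hypoxia response and glycolysis (24 measured, list adjusted p = 0.0823), oxidative phosphorylation (29, 0.155) or the unfolded protein response (23, 0.921) passed, over all genes or adjusted over the list alone. The hypoxia list had an adjusted p of 0.0111 without hyperoxia pup 13-2 and 0.0471 without normoxia pup 13-10, and the oxidative phosphorylation list 0.0148 without normoxia pup 13-10. The leading values of the first were Car9 at 0.56, Egln3 at 0.79, Slc16a3 at −0.21 and Mxi1 at −0.37. Those of the second were Ndufb8 at −0.30, Uqcrb at 0.21, Cox8a at −0.17 and Ndufs1 at 0.19, and those of the third Dnajb9 at −0.24, Pdia4 at 0.16, Asns at −0.17 and Pdia6 at 0.12.

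The tested lists of markers of other cell types had median levels from 3.92 (endothelial) to 6.41 (mesothelial). Of 17 epithelial markers, with a median level of 4.47, 0 passed and 12 had values above 0. The list adjusted p was 0.0152, and adjusted p = 0.621 with an estimated correlation, with 3 higher and 0 lower when adjusted over the list alone. Those 3 were the simple-epithelium keratins Krt7, at 10.51 ± 0.043 against 9.89 ± 0.24 (SD, n = 3 pups; log2 fold change 0.62, SE 0.12, adjusted p = 0.0667), Krt8 (0.46, SE 0.097, adjusted p = 0.0926) and Krt18 (1.07, SE 0.23, adjusted p = 0.0993), with Elf3 at 0.21. Of 10 mesothelial markers Upk1b rose and 9 did not pass, with Upk3b at 1.26 (SE 0.40, adjusted p = 0.221), Wt1 at −0.63 and Cdh3 at −0.31. Over the list, camera gave an adjusted p of 0.484, and the calls adjusted over the list alone were 2 higher and 2 lower. Of 8 glial and neural markers Tubb3, a tubulin also found in cultured cells outside the nervous system, fell by 0.51 (SE 0.072, adjusted p = 0.0313) and 7 did not pass, with S100b at 0.76, Gap43 at −0.13 and Sox10 at 0.15. Camera returned an adjusted p of 0.459 for the list, and 1 higher and 1 lower passed when adjusted over the list alone. None of the leukocyte (19 measured, list adjusted p = 0.167), endothelial (15, 0.321), cartilage (10, 0.227) or muscle (9, 0.459) markers passed, over all genes or adjusted over the list alone. Lyz2 stood at 0.99 (SE 0.30, adjusted p = 0.206) and Laptm5, C1qa and Cd14 at 0.15, 0.099 and 0.13 among the first. Among the second Tek stood at 0.49, Egfl7 at −0.094, Sox17 at 0.12 and Esam at 0.29. Col9a2, Col9a1, Col2a1 and Matn3 stood at 0.13, 0.31, 0.37 and −0.13, and Myog, Acta1, Myl7 and Myf5 at −0.16, −0.43, −0.12 and −0.17. Of the sex-linked genes only Uty was measured, at 7.37 ± 0.05 against 7.64 ± 0.27 (adjusted p = 0.378), and the list was not tested. Its values were 7.39, 7.31 and 7.40 in hyperoxia pups 13-1, 13-2 and 13-3. Normoxia pups 13-10 and 13-11 stood apart at 7.78 and 7.82, with 13-13 at 7.33. Whether the sex of the pups differed between the groups was not tested, and 1 gene cannot settle it.

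**Figure D3:**
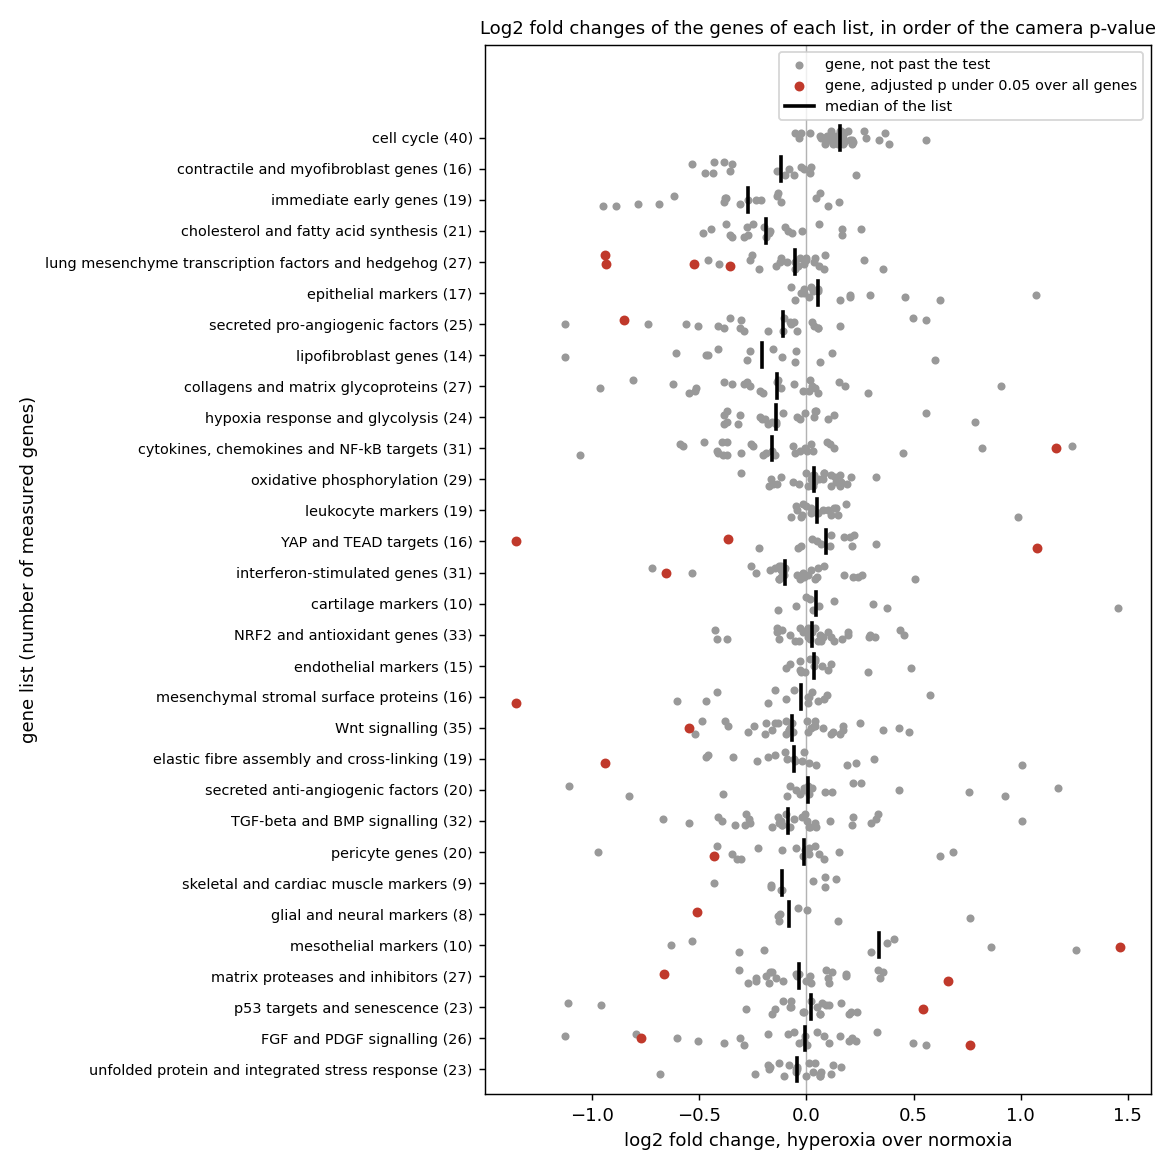
Log2 fold change (hyperoxia over normoxia) of each measured gene of the 31 tested lists, ordered by the camera p-value from top to bottom; red points passed an adjusted p of 0.05 over all genes and black bars mark list medians. Cell cycle genes (median 0.16) sit mostly right of 0 and immediate early genes (median −0.27) mostly left, with no red point in either, and 4 red points mark the fallen genes of the lung mesenchyme transcription factor and hedgehog list.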

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

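The tests of the RT1 genes and of the epithelial and mesothelial markers, and the fit without 1 array, were chosen after the results were seen, as was the use of the estimated correlation, itself a planned setting, to test the cell cycle and immediate early lists; the other tests in this part were not. Among 52 groups of 9 arrays, 2 held an array that stood apart by Dixon's test (critical value 0.493). The values tested were the array medians, each array's mean correlation with the others of its group, and the 12 genes with the largest changes in each direction. Chance gives about 1 in 20 among independent values. The 9 arrays of a group came from 3 pups, so that rate need not hold here. Array 2 of hyperoxia pup 13-3 had a mean correlation of 0.9912 with the other arrays of its group, against 0.99294 to 0.99393 for the others; without it 184 genes and 8 lists passed. Sprr1a stood at 6.31 on array 1 of normoxia pup 13-11, against 6.58 to 6.75 on the other normoxia arrays. When every probe set was tested on its own, 4 of the 30 past the threshold carried no single gene symbol, and all 4 were lower in hyperoxia; the largest changes among them were −1.05 (probe set 17688142) and −0.75 (probe set 17757234).

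RT1-CE16 and RT1-CE15 had the largest changes in value, from normoxia levels within the range of the receptor genes. A signal from probes shared with other RT1-CE genes would raise these too, but the other 8 had a median log2 fold change of 0.072 (SD over genes 0.17), and an induction of class I antigen presentation was not seen in B2m, Tap1, Nlrc5 and 6 others (median −0.101, SD 0.24). Inherited RT1 haplotypes stay open: in an outbred stock the pups of each group may carry other RT1 genes, or sequence variants under the probes, whatever they breathed. Genes of the RT1 cluster other than these were past the threshold in 3 of 145 (G4, Psmb8 and RT1-DMa) against 177 of 17912 elsewhere, an odds ratio of 2.12 with a 95% interval of 0.427 to 6.41 (Fisher's exact test, two-sided p = 0.176), too wide to tell haplotype from exposure. Litters and genotypes are not in the sources used here, and an effect of hyperoxia itself remains untested.

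The keratins Krt7, Krt8 and Krt18 and the uroplakins Upk1b and Upk3b had higher values in hyperoxia, of which Upk1b passed over all genes. Dim probe sets did not read higher on hyperoxia arrays as a whole, the receptor genes having a median of −0.0549. More epithelial cells stay open: the other 14 epithelial markers had a median log2 fold change of 0.0259 (SD 0.11), but 7 of them lie in the range of the receptor genes, among them Epcam (level 2.15), and Cldn18, Cdh1, Nkx2-1 and Sftpc lie close above it (4.45 to 4.57), where a small share of such cells need not show. The 3 markers well above that range rose little or not at all: Abca3 (level 6.63) at −0.012, Cldn3 (6.44) at 0.20 and Ager (5.10) at 0.052. Whether their signal came from epithelial cells was not tested, so these 3 do not settle the question. More mesothelial cells stay open as well: the other 8 mesothelial markers had a median of 0.0509, but they went both ways (SD 0.53), with Aldh1a2 at 0.86, Krt19 at 0.41, Lrrn4 at 0.38, Msln at 0.30, Bnc1 at −0.20, Cdh3 at −0.31, Gpm6a at −0.54 and Wt1 at −0.63. Relative to the mean of all pups the mesothelial list stood at 0.275 and 0.462 in hyperoxia pups 13-1 and 13-2 and at −0.29 in 13-3, against −0.322 to −0.0101 in normoxia, and Upk3b stood at 7.24, 7.55 and 5.86 in the 3 hyperoxia pups. The cells had been sorted for CD146, and Mcam stood at 9.62 in hyperoxia against 9.47 in normoxia. That value cannot show whether a small share of other cells was present. Other cells in the cultures and a change in the stromal cells cannot be told apart here, and litter and exposure remain untested.

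Cell cycle genes were higher and immediate early genes lower in hyperoxia as lists with a preset correlation. Leaving out 1 of the 6 pups, hyperoxia pup 13-3, ended the call of the cell cycle list (adjusted p = 0.107), and leaving out the same 1 pup ended that of the immediate early list (adjusted p = 0.25). With an estimated correlation between genes, a test with little power here, both had an adjusted p of 0.644. The estimates were 0.83 for the cell cycle list and 0.561 for the immediate early list, against a preset 0.01. Correlation between the genes of these lists can thus account for their calls with the preset value. Without hyperoxia pup 13-3 only 2 of the 8 lists passed, so the loss was not particular to these lists. Jun and Myc were lower in every hyperoxia pup than in any normoxia pup, while Nr4a2 and Klf4 overlapped between groups. A difference in growth state of 1 culture, through genes that move together, and an effect of exposure cannot be told apart. The labels give no cell density for each pup.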

How the results depend on the processing

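The fit without array 2 of hyperoxia pup 13-3 and the values of single lists under quantile normalization and with array medians subtracted were chosen after the results were seen; all others were planned. The count of 183 genes past the threshold moved. It was 30 (56.7% higher) with every probe set on its own, which adjusts for more tests and also refits the variance prior, 1001 with array weights, 1739 with 18 arrays and the pup as a random block, and 3782 (47.1% higher) with arrays taken as independent, which counts technical arrays as animals. With the technical replicate number as a further block it was 1536. Both fits with the pup as a random block take error degrees of freedom from single arrays and use the same correlation for all genes. Their counts can therefore be too high for a comparison between pups. Arrays with the same number had deviations that correlated by 0.042, 0.0197 and 0.0138 on average, against −0.0126 for other numbers. Any pairing of arrays by number was thus weak, and it was not tested. Only technical array 1, 2 or 3 of each pup gave 69, 60 (55% higher) and 102 genes; with fewer arrays the error is larger. Other thresholds gave 414 (adjusted p under 0.1), 97 and 34 (at least 1.5-fold and 2-fold) and 2613 (unadjusted p under 0.05). Subtracting array medians gave 225 genes, 31.1% of them higher. Leaving out a pup gave 18 to 263 genes (38% to 77.8% higher), with fewer samples, and 2 to 11 lists. Gene lists past the threshold numbered 0 with an estimated correlation, 0 with fry and 4 with camera on ranks. The consensus correlation of technical arrays, 0.465, was 0.737 among genes above the 50th percentile of the mean level. In the other settings counts of genes and lists stayed within 1.5 times.

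Of all values of named genes under the alternatives, 2705 kept their direction and side of the threshold, 330 came to pass it, 173 no longer passed it and 5 changed direction, none of them past the threshold: C1qa was at −0.0047 with only technical array 2 of each pup, Laptm5 at −0.0059 and Myl7 at 0.035 with only array 3, and on leaving out a pup Thy1 ranged from −0.027 to 0.15 and Cdkn1a from −0.028 to 0.13. Lists without a call that turned on leaving out a pup had adjusted p from 0.275 to 0.993 (p53 targets), 0.632 to 0.916 (FGF and PDGF, which also turned, at 0.899, with array medians subtracted), 0.024 to 0.685 (elastic fibres), 0.232 to 0.909 (matrix proteases) and 0.683 to 0.916 (unfolded protein response). The cause was not tested for any of these. Signal over background limits the dim genes: 11 of the 183 had a mean level below 4.45.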

Other observations

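The genes of this paragraph and the pairs of neighbours were singled out after their values were seen; the tests of neighbours and of other splits of the pups were set out before their results. Outside the fixed lists, further single genes passed the test in limma in both directions. The Notch ligand gene Jag1 rose by 0.58 (SE 0.066, adjusted p = 0.0178) and the Notch feedback gene Nrarp by 0.51 (SE 0.079, adjusted p = 0.039). The semaphorin gene Sema7a rose by 0.94 (SE 0.11, adjusted p = 0.0213) and the plexin gene Plxna2 by 0.54, while Plxnd1 fell by 0.70 (adjusted p = 0.0213). The connexin gene Gjb5 rose by 1.20 (SE 0.13, adjusted p = 0.0148), the claudin gene Cldn15 by 0.63 and the EGF receptor ligand gene Btc by 0.89. Emilin2, a matrix glycoprotein gene, rose from 6.15 ± 0.0078 to 6.88 ± 0.0027 (SD, n = 3 pups; adjusted p = 0.00339). The cytokine gene Il15 fell by 0.58 (SE 0.072, adjusted p = 0.0213), the receptor genes Il4r and Il1rl2 by 0.66 and 0.53, and the class II chaperone gene RT1-DMa by 0.82 (SE 0.11, adjusted p = 0.0213). Stc2, which encodes stanniocalcin 2, fell by 0.81, the neurotrophic factor gene Gdnf by 0.51 and the fibroblast surface gene Lrrc15 by 0.98 (adjusted p = 0.0475). No list of these was tested for enrichment.

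Of the genes past the threshold, 4 pairs were next to one another among 18059 placed genes: RT1-CE16 and RT1-CE15, Sncg and Mmrn2, Il1rn and Psd4, and Dact3 and Gng8, each pair with the same sign. Random sets of the same size gave a median of 2 pairs and a 95th percentile of 4, and a share of 0.107 of 10000 sets gave as many. Linked inherited differences between the pups of the groups may add such pairs, but 4 lies between the bounds that were set, so inherited and other sources cannot be told apart here.

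The 6 pups can be split in 10 ways, too few for a share under 0.05. The real split gave 183 genes past the threshold and the highest of the other splits 0, so 1 of the 10 gave as many; the others had up to 2180 genes at an unadjusted p under 0.05 against 2613. For gene lists the real split gave 8 and the highest other 7, so again 1 of the 10 gave as many.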
